A study of Mus musculus with 6 samples.

How the data were processed

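RNA of flow-sorted mouse bone marrow cells was measured on 6 Affymetrix arrays, 3 from each of 2 genotypes. Per the labels' protocols, cKit-positive cells that carried the MLL-AF9 fusion, an oncogene of acute myeloid leukaemia, together with a yellow fluorescent protein (YFP) marker were transplanted into irradiated wild-type recipients aged 12 weeks. Each recipient got 50000 such cells and 250000 wild-type support marrow cells. At 4 weeks after transplantation the mice received 2 injections of tamoxifen at 0.2 mg per g of body weight, and they were analysed 6 days after the last injection. The sorted population, named LGMP in the labels, was lineage-negative, cKit-positive, Sca1-negative, YFP-positive, CD34-positive and FcgRII/III-positive. Total RNA (5 ng) was amplified with the NuGEN Ovation system and labelled with biotin.

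The values deposited by the authors are intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name RMA, a method that corrects background, normalizes arrays by quantiles and summarises probes, and its version is not given in the sources used here. The intensities ran from 3.60 to 24044 over the 6 arrays, and the array medians from 49.6 to 51.0. The sorted values of each array lay within 0.103 of the mean array on the log2 scale, so the arrays had been brought to nearly 1 distribution before deposit. Such a step removes any difference in total signal between groups, and changes are relative to the other genes of an array. RMA results are usually on a log2 scale, and the design chosen before the data were examined provided for taking log2 first if they were not. That was done here, with no added offset. Detection calls and scanner files were not used here, and no batch, array date or slide was used. The number of arrays limits the precision.

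Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none, of which 64 were Affymetrix controls. Of the named probe sets, 34754 had an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, from which chromosomes and the order of neighbouring genes were taken. Coordinates are not printed. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18194 genes. Values of a gene are those of this brightest probe set unless another is named.

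N1-IC arrays were compared with WT arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, trend and robust settings off, no replicate block), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 fold changes are limma's moderated standard errors. Group values are means of log2 intensities with the SD over 3 arrays. The 28 gene lists were written from general knowledge before the data were examined, and 394 of their 430 genes were measured. The 25 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The lists of Y-linked genes, of sort gate genes and of genes of the engineered alleles had fewer members and are described gene by gene. Camera with an estimated correlation and fry, which tests a list by itself without comparing it with other genes, were the alternatives.

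The genes named in the text follow a rule fixed at the same time. It takes the 10 genes with the highest and the 10 with the lowest log2 fold change among those past the threshold whose groups do not overlap, filled up to 10 per direction by the smallest unadjusted p. It adds all measured members of the lists of Notch targets, genes of the engineered alleles, Y-linked genes, X inactivation genes, sort gate genes and CDK inhibitors, and up to 4 members with the smallest p of every other list. A few genes outside this rule are named and marked as chosen after their values were seen. Other alternatives were a mean-variance trend, a robust prior, array weights, a further quantile normalization, centring on array medians, a filter at the median gene level, the mean of a gene's probe sets, all probe sets, a replicate block, each array left out, thresholds of 0.1 and 0.01, a minimum fold change of 1.2, and X- and Y-linked genes left out.

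The fit was tested on simulated data with the real gene means, 18194 genes and 200 changed genes in each of 10 runs. With spreads drawn from the prior that limma fitted to the real arrays, 59.2% of genes changed by 1 on the log2 scale, 88.0% of those changed by 2, 97.0% of those changed by 4 and 99.6% of those changed by 6 were recovered, and 5.27% of the calls were unchanged genes. A list of 20 genes shifted by 0.5 was called in 10 of 10 runs, with 0 calls among the unshifted lists. The simulated genes varied independently of each other, unlike the genes of a real list. No simulated array stood apart from its group, so these shares do not say which real changes would be found. In the real limma fit Adamdec1, Xist, Kdm5d and Uty did not pass (adjusted p of 0.0714, 0.618, 0.206 and 0.0678). Their log2 fold changes were 8.43, 5.52, -4.91 and -4.32. Figures were drawn with matplotlib 3.10.9.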

Results

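The series measured gene expression in MLL-AF9 LGMP, the sorted progenitor cells of a mouse leukaemia model. In one of the genotypes tamoxifen was meant to switch on the Notch pathway. Notch is a cell-surface receptor whose intracellular domain moves to the nucleus and activates transcription. The N1-IC group (n = 3) carried an inducible intracellular domain of Notch1 in the EF1α locus, and the WT group (n = 3) carried the unmodified locus. Both groups carried the tamoxifen-dependent Cre recombinase CreERT2 in the ROSA locus and both were given tamoxifen. By the labels all 3 WT samples were male and all 3 N1-IC samples were female, so genotype and sex coincide in every comparison. The labels do not say how many recipients stood behind a sample, and the p-values measure the spread between these samples. Array medians lay between 49.6 and 51.0 intensity units. Across genes, array values correlated at 0.9849 to 0.9894 within WT, at 0.9896 to 0.9924 within N1-IC and at 0.9832 to 0.992 between the groups. WT replicate 3 correlated at 0.9894 and 0.9884 with WT replicates 1 and 2. With N1-IC replicates 1, 2 and 3 its correlations were higher, at 0.992, 0.9901 and 0.9908.

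The comparison of N1-IC with WT asked which genes differed between the genotypes after tamoxifen. The Y-linked translation factor gene Eif2s3y was the single gene past the threshold. It fell from 10.97 ± 0.546 (SD, n = 3) to 3.22 ± 0.262 (SD, n = 3) log2 units in N1-IC, with a log2 fold change of -7.75 ± 0.29 (standard error) and a limma adjusted p of 0.00229. No autosomal gene passed in this fit. The autosomal genes nearest to the threshold were Adamdec1, which encodes a secreted metalloprotease of the ADAM family, and Nrn1, which encodes the membrane-anchored protein neuritin. Adamdec1 had log2 values of 3.72, 3.73 and 3.05 on the WT arrays and 10.27, 12.68 and 12.86 on the N1-IC arrays, a log2 fold change of 8.43 ± 0.70 with an adjusted p of 0.0714. The WT values of Adamdec1 and the N1-IC values of Eif2s3y lay below the lower quartile of their arrays (14.5 to 15.1 intensity units). Detection calls were not used here, so whether they exceed background is unknown and the size of both fold changes is uncertain. Nrn1 had means of 7.06 ± 0.0697 in WT and 8.48 ± 0.16 in N1-IC (SD), with an adjusted p of 0.0678. Under other settings Adamdec1 passed with a mean-variance trend (adjusted p = 0.0304), with the mean of a gene's probe sets (0.042) and without N1-IC replicate 1 (0.0026). Nrn1 passed with the mean of a gene's probe sets (0.036) and among genes at or above the median level (0.0499). Both genes have 1 probe set, so taking means changed the values of other genes and not theirs. Their log2 fold changes were the same in each of these settings that left no array out.

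Further genes selected by the smallest p did not pass, each with an adjusted p of 0.541 or 0.618. Among them Pla2g7, which encodes a secreted phospholipase, had a log2 fold change of 3.73 ± 0.61, Mid1 one of 1.77 ± 0.30 and Abcg3, of the ABC transporter family, one of 1.76 ± 0.25. Mid1 lies on chromosome X, and all N1-IC samples were female and all WT samples male. The other probe sets of Mid1 had log2 fold changes of 0.079 and 0.074. Gm49249, Dok2, Oasl2, Slc13a2 and Gchfr had log2 fold changes of 1.29, 0.91, 0.85, 0.74 and 0.61. On the lower side Lrmda had a log2 fold change of -3.33 ± 0.46 (adjusted p = 0.00806 without N1-IC replicate 2), Apoe, which encodes the lipid carrier apolipoprotein E, one of -1.70 ± 0.21, and Klrb1f, Bcl6b, Ube4a, S1pr4 and D17H6S56E-5 had -0.98, -0.89, -0.73, -0.70 and -0.51. By the brightest probe set the 3 arrays of one group did not overlap those of the other for any of these genes, and 1 of the 3 probe sets of Ube4a had the opposite sign. Over all 18194 genes, 2701 (14.8%) had groups that did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 1452 genes, 753 higher and 699 lower in N1-IC, where 910 would be expected by chance. The count past the adjusted threshold depended on single arrays: it was 5 without WT replicate 2, 0 without WT replicate 3, 2 without N1-IC replicate 1 and 3 without N1-IC replicate 2. With X- and Y-linked genes left out it was 0.

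**Figure D1:**
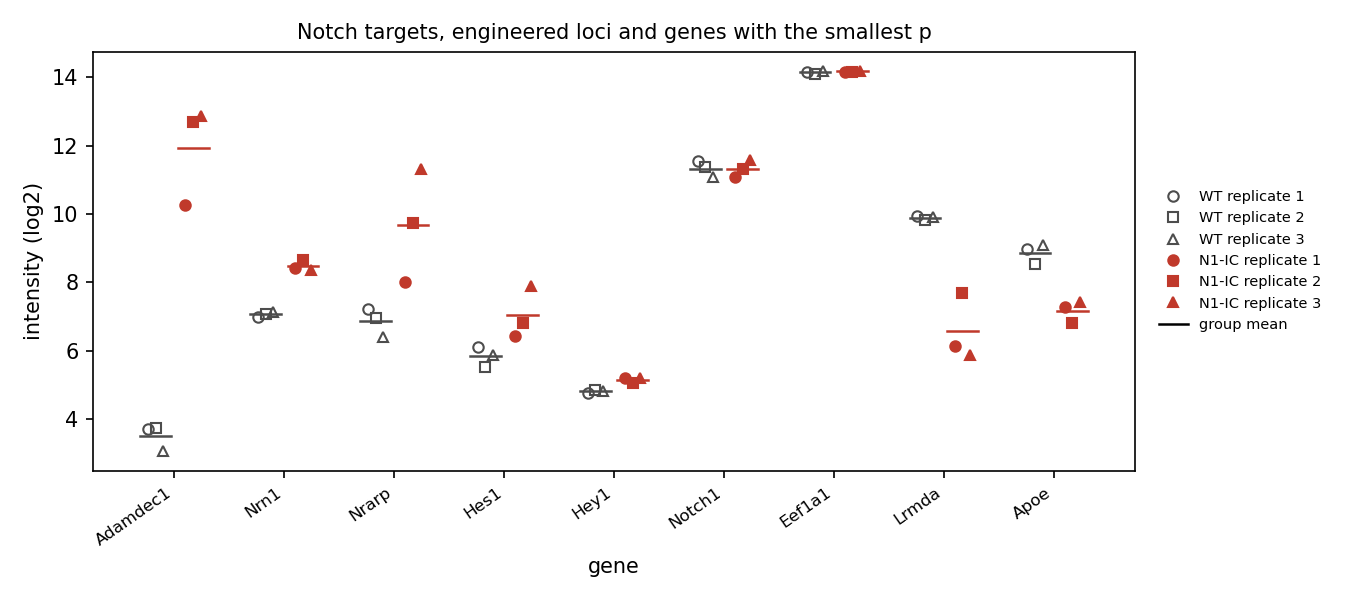
Log2 intensity (vertical axis) of 9 genes on each array, with WT as open grey and N1-IC as filled red symbols, the symbol shape giving the replicate number and lines giving group means. Adamdec1 lies at 3.05 to 3.73 on the WT arrays and at 10.27 to 12.86 on the N1-IC arrays, Nrarp at 6.41 to 7.22 and 8.01 to 11.33, and Notch1 and Eef1a1 overlap between the groups.

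The Notch target genes asked whether the induced domain left a trace in known targets. Of 18 measured members 11 had a higher and 7 a lower mean in N1-IC, and 0 passed either over all genes or adjusted over the list alone, where the smallest adjusted p was 0.103. Nrarp, which encodes a feedback inhibitor of Notch signalling, had log2 values of 6.41 to 7.22 in WT and of 8.01, 9.74 and 11.33 in N1-IC, a log2 fold change of 2.83 ± 0.80. The transcriptional repressor gene Hes1 had a log2 fold change of 1.203 ± 0.38 and its relative Hey1 one of 0.35 ± 0.09. By the brightest probe set all 3 genes were higher on every N1-IC array than on every WT array, with unadjusted p values of 0.0114, 0.0192 and 0.00763 and an adjusted p of 0.618 each. The other probe set of Nrarp overlapped between the groups, at 3.57 to 5.78 in WT and 4.69 to 8.52 in N1-IC. Hes5, Heyl, Dtx1, Ptcra and Il2ra had log2 fold changes between -0.19 and 0.17, and Myc and Ccnd1 had -0.55 and 0.81 with overlapping groups. Heyl, Dtx1, Ptcra and Il2ra lay at 3.18 to 4.33 log2 units, below the array medians of 5.63 to 5.67. Whether these low values exceed background is unknown, so they do not show that expressed targets failed to respond. The list as a whole was not called as shifted against other genes (camera adjusted p = 0.44, and adjusted p = 0.91 with an estimated correlation). Fry's test of the list by itself gave an adjusted p of 0.00405 without regard to direction and of 0.726 with direction, and it says of no single member that it changed.

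Among genes of the engineered alleles 0 of 4 passed, over all genes or adjusted over the list alone. Notch1 had a mean of 11.33 in both groups and a log2 fold change of -0.004 ± 0.18. Which part of Notch1 its probe sets cover was not analysed here, so they do not check the induced domain. Eef1a1, the gene of the EF1α locus, had a log2 fold change of 0.03 ± 0.08. The fusion partner genes Kmt2a and Mllt3 had log2 fold changes of -0.51 ± 0.19 and -0.49 ± 0.55. Kmt2a was lower on every N1-IC array than on every WT array by its brightest probe set (unadjusted p of 0.034, adjusted p of 0.618), and its other probe set overlapped between the groups. Notch receptors, ligands and pathway enzymes were not called as a list (camera adjusted p = 0.826), with 9 of 22 members higher and 13 lower.

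Xist and the genes of the Y-linked list separated the groups in the direction of the stated sexes, with a departure on the array of WT replicate 2. The 3 measured genes of the Y-linked list, of 9 genes measured on chromosome Y, were lower in N1-IC on every array, and all 3 passed when adjusted over the list alone. None of the other 6 was lower in N1-IC on every array. Beside Eif2s3y, Uty had a log2 fold change of -4.32 ± 0.32 and Kdm5d, a histone demethylase gene, one of -4.91 ± 0.51, with adjusted p values over all genes of 0.0678 and 0.206. Their N1-IC values also lay below the lower quartile of the arrays, so the size of these fold changes is uncertain too. Xist, the non-coding RNA that silences an X chromosome in female cells, was at 12.73 to 12.82 on the N1-IC arrays. On the WT arrays it was at 5.64, 10.70 and 5.42 for replicates 1, 2 and 3, and over all 6 arrays its adjusted p was 0.618. Without WT replicate 2 its log2 fold change was 7.25 with an adjusted p of 0.000184. WT replicate 2 also had the lowest WT values of Eif2s3y (10.34), Uty (6.70) and Kdm5d (6.88) by the brightest probe sets. The X inactivation list, with 9 of 10 members higher and 4 passing when adjusted over the list alone, was called higher in N1-IC (camera adjusted p = 0.0378, but adjusted p = 0.91 with an estimated correlation). Eif2s3x, Kdm6a and Kdm5c, X-linked genes known to escape inactivation, had log2 fold changes of 0.30, 0.66 and 0.28. The list's call ended without WT replicate 3 (adjusted p = 0.272), N1-IC replicate 1 (0.129) or N1-IC replicate 3 (0.086).

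**Figure D2:**
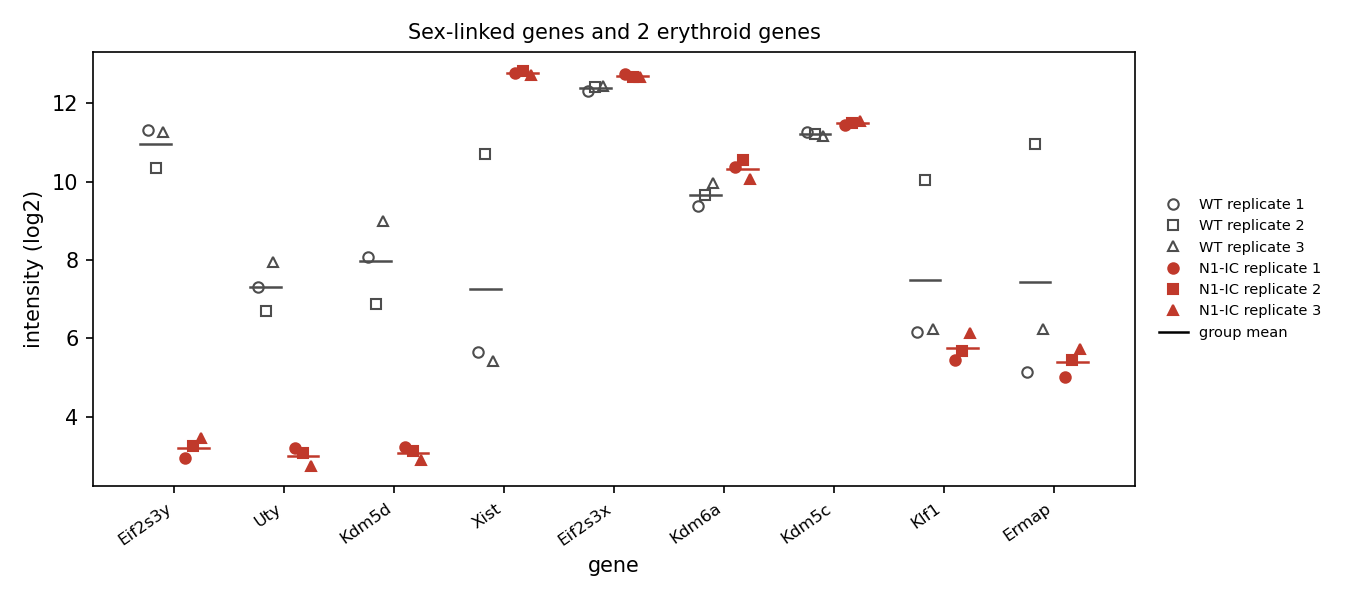
Log2 intensity (vertical axis) of 3 Y-linked genes, Xist, 3 X-linked escape genes and the erythroid genes Klf1 and Ermap on each array, with WT as open grey and N1-IC as filled red symbols, shapes giving the replicate number and lines giving group means. WT replicate 2 has Xist at 10.70 and Ermap at 10.97, above the other WT arrays, and the lowest WT values of Eif2s3y, Uty and Kdm5d.

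Of the 25 tested lists, camera called 4: ribosome biogenesis and MYC targets lower, and interferon-stimulated, late granulocyte and X inactivation genes higher in N1-IC. With an estimated correlation 0 were called, each with an adjusted p of 0.91 or more, and fry's directional test called 0. Fry without regard to direction gave an adjusted p of 0.00405 for the interferon-stimulated, X inactivation and Notch target lists. Ribosome biogenesis and MYC target genes had 18 of 21 members lower (camera adjusted p = 0.00173, and adjusted p = 0.91 with an estimated correlation), with a mean log2 fold change of -0.17. The list mean was 10.91, 10.82 and 11.09 on the N1-IC arrays, so replicate 3 lay within the WT range of 11.08 to 11.17. None of the genes passed alone. Srm, which makes spermidine, had -0.41 ± 0.13, and the nucleolar genes Nop2, Ppan and Nop56 had -0.37, -0.52 and -0.24. The call ended without N1-IC replicate 2 (adjusted p = 0.0752).

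Interferon-stimulated genes had 15 of 19 members higher (camera adjusted p = 0.0204, and adjusted p = 0.91 with an estimated correlation), with a mean log2 fold change of 0.30. The list mean was 6.75, 7.11 and 7.02 on the N1-IC arrays, so replicate 1 lay within the WT range of 6.54 to 6.83. The antiviral genes Oasl2, Oas2 and Ifit1 had log2 fold changes of 0.85 ± 0.13, 0.92 ± 0.22 and 0.81 ± 0.21. Mx1, of the same pathway, had -0.84 ± 0.26. In the list 3 members passed when adjusted over the list alone, all higher, and 0 passed over all genes. The call ended without WT replicate 3 (adjusted p = 0.328), without N1-IC replicate 2 (0.109) and without N1-IC replicate 3 (0.0585), and among genes at or above the median level (0.095).

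Late granulocyte genes, which encode secondary granule and mature neutrophil proteins, had 15 of 17 members higher (camera adjusted p = 0.0461, and adjusted p = 0.91 with an estimated correlation). Mmp9, a gelatinase gene, had a log2 fold change of 2.71 ± 0.84, Il1r2 one of 1.18 ± 0.63 and Lcn2 one of 0.86 ± 0.57, and none passed alone. The mean of the list was 8.01 in WT replicate 1, against 10.30 and 10.06 in WT replicates 2 and 3 and 10.28, 10.50 and 10.04 in N1-IC. Without WT replicate 1 the mean log2 fold change was 0.089 with an adjusted p of 0.922. The call also ended without N1-IC replicate 1 (0.129), 2 (0.153) or 3 (0.0585) and with arrays centred on their medians (0.0674). Primary granule genes, expressed at the promyelocyte stage, lay at 12.87 to 13.18 on the 6 arrays and were not called (adjusted p = 0.44).

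**Figure D3:**
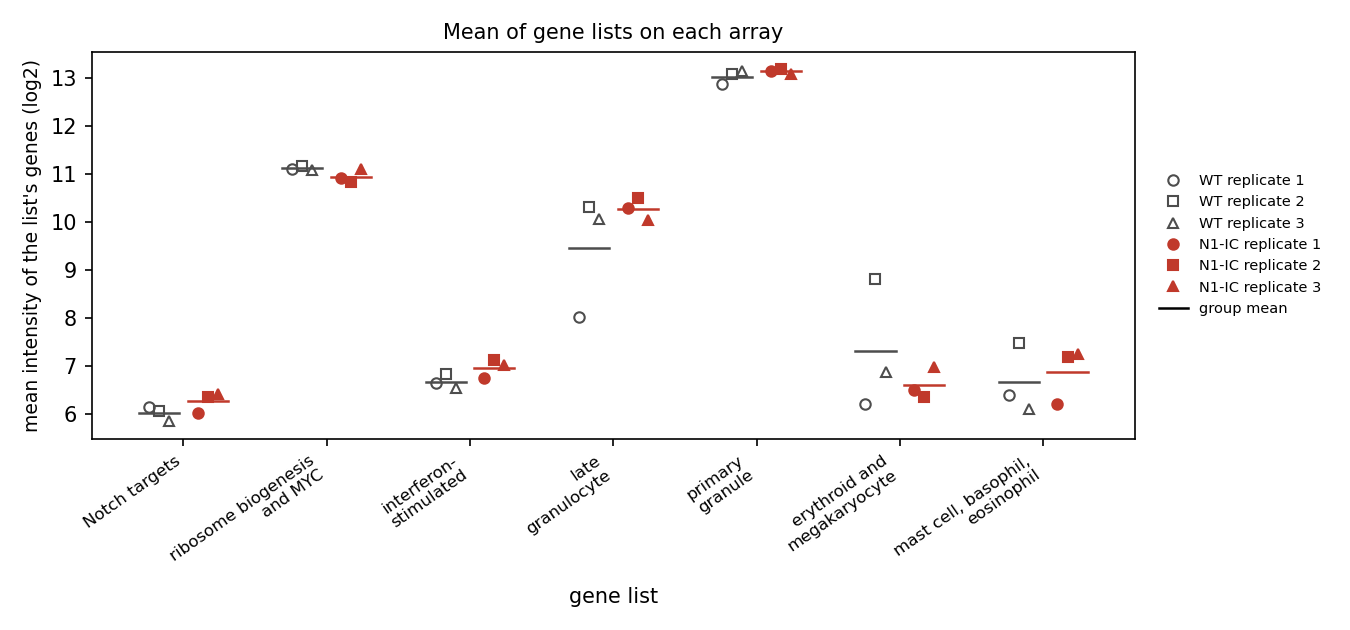
Mean log2 intensity of the genes of 7 lists (vertical axis) on each array, with WT as open grey and N1-IC as filled red symbols, shapes giving the replicate number and lines giving group means. WT replicate 1 lies at 8.01 for late granulocyte genes, where the other arrays lie between 10.04 and 10.50, and WT replicate 2 lies at 8.81 for erythroid and megakaryocyte genes, where the others lie between 6.21 and 6.97.

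Markers of other cell types were examined because the sort could hold them, and over all 6 arrays 0 of these lists passed beside the late granulocyte list. Erythroid and megakaryocyte genes had a mean of 8.81 in WT replicate 2, against 6.21 to 6.97 on the other arrays (camera adjusted p = 0.44). Without WT replicate 1 this list was called lower in N1-IC (adjusted p = 0.0137, mean log2 fold change -1.24), but with an estimated correlation the adjusted p was 0.782. Without WT replicate 2 its mean log2 fold change was 0.067. The erythroid transcription factor gene Klf1 was at 10.04 and Ermap at 10.97 in WT replicate 2, against 5.46 to 6.25 and 5.02 to 6.23 elsewhere. Mast cell, basophil and eosinophil genes had means of 7.47 in WT replicate 2, 7.18 in N1-IC replicate 2 and 7.24 in N1-IC replicate 3, against 6.09 to 6.40 elsewhere (adjusted p = 0.571), and were called higher in N1-IC without WT replicate 2 (adjusted p = 0.0496, but adjusted p = 0.808 with an estimated correlation). T lineage genes had a mean log2 fold change of 0.02 (adjusted p = 0.571) and B lineage genes one of 0.21 (0.443), with Cd22, a B cell lectin gene, at 2.08 ± 0.64. The NK and cytotoxic list had -0.23 (adjusted p = 0.241), with the receptor gene Klrk1 at -1.32 ± 0.34. The monocyte and macrophage list had 0.06 (0.571), the dendritic list -0.015 (0.826), and the stromal and endothelial list -0.04 (0.826). Of 9 MHC class II genes 4 were higher and 5 lower in N1-IC (list adjusted p = 0.571). Among them 1 passed when adjusted over the list alone, H2-Aa, with a log2 fold change of 0.80 ± 0.15. Cd74, the invariant chain gene, had 1.65 ± 0.52. H2-DMa had -0.46 ± 0.18 and by its brightest probe set was lower on every N1-IC array than on every WT array.

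Genes of the sort gate, of leukaemia and of stem cells gave no call. Cd34 had a log2 fold change of -0.72 ± 0.32, Fcgr3 -0.25, Fcgr2b -0.16 and Kit -0.003, and none passed. The MLL-fusion program had 13 of 19 members higher (adjusted p = 0.571), with the anti-apoptotic gene Bcl2 at -0.94 ± 0.33, and haematopoietic stem cell genes had 5 of 14 members higher (adjusted p = 0.698), with the transcription factor gene Gata2 at -1.35 ± 0.57. DNA replication genes (adjusted p = 0.571) and mitosis genes (0.826) were not called over all 6 arrays, and DNA replication genes were called lower without WT replicate 1 (adjusted p = 0.0347, but adjusted p = 0.711 with an estimated correlation). Of 7 CDK inhibitor genes Cdkn2c, which encodes p18, had the smallest p, with a log2 fold change of 1.61 ± 0.44 and all 3 N1-IC arrays above the WT arrays. Cdkn1a, Cdkn1b and Cdkn2a had -0.47, -0.02 and 0.16, and the list had an adjusted p of 0.932. The probe sets of Cdkn1b disagreed. Its other probe set had a log2 fold change of 0.517, with every N1-IC array above every WT array (limma unadjusted p of 0.00887, adjusted p of 0.639 over all probe sets).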

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

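Probe sets without a single gene name stayed outside the gene comparison. When all 45101 probe sets were fitted together in limma, 3 of these passed an adjusted p under 0.05, all 3 lower in N1-IC. On the WT arrays the first lay at 10.45, 10.12 and 10.48 log2 units and on the N1-IC arrays at 2.55, 2.73 and 2.97 (adjusted p = 0.000152). The other probe sets had log2 fold changes of -6.45 and -3.32 with adjusted p values of 0.000808 and 0.00894. Their genes are not named here and no explanation was tested.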

How the results depend on the processing

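The number of genes past the threshold was 1 with a robust prior, renewed quantile normalization, median centring, a threshold of 0.01 and a minimum fold change of 1.2. It was 3 with a mean-variance trend (1 higher, 2 lower), 2 with array weights (0 higher, 2 lower), 2 among genes at or above the median level (1 higher, 1 lower), 5 with the mean of a gene's probe sets (2 higher, 3 lower), 4 among all probe sets (0 higher, 4 lower), 4 at a threshold of 0.1 (2 higher, 2 lower) and 0 with X- and Y-linked genes left out (0 lower). Leaving out 1 array at a time gave 0 to 5 genes, 0 to 1 higher and 0 to 4 lower, and 0 to 4 sex-linked genes, with the highest counts without WT replicate 2 and the lowest without WT replicate 3. The next settings were chosen after seeing the data. With WT replicates 1 and 2 both left out, where the lone WT array is assumed to vary like the N1-IC arrays, 3 genes passed (1 higher, 2 lower), all 3 sex-linked, and leaving out the erythroid, late granulocyte and mast cell lists gave 1.

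Deviations of same-numbered arrays from their group means correlated at 0.009, 0.061 and -0.11 across genes. No strong shared effect of the replicate number was seen, which does not show that the samples were unpaired. With a replicate block 0 genes passed (0 lower) and 3 lists were called, with an adjusted p of 0.0684 for the X inactivation list.

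Camera's 4 called lists became 0 with an estimated correlation (adjusted p = 0.91 for each) and 0 by fry's directional test (0.905 for late granulocyte, 0.592 for interferon-stimulated, 0.715 for ribosome biogenesis and MYC, 0.0771 for X inactivation genes). Fry without regard to direction called 3 lists, Notch target, interferon-stimulated and X inactivation genes (0.00405 each). Median centring ended the late granulocyte call (0.0674) and the level filter the interferon call (0.095). Leaving out 1 array at a time gave 1 to 5 called lists and adjusted p values of 0.000406 to 0.922 for late granulocyte, 0.00179 to 0.328 for interferon-stimulated, 1.47e-05 to 0.0752 for ribosome biogenesis and MYC and 0.00179 to 0.272 for X inactivation genes. With WT replicates 1 and 2 both left out 8 lists were called, late granulocyte genes not among them (0.443), and immediate early genes, on balance lower over all arrays, were called higher (0.0238). For that fit, which kept 1 WT array, camera was run at the preset correlation alone. The Notch target list was not called in any of 15 alternatives that test direction (0.129 to 0.91). Beyond the smaller number of arrays or genes in some settings, the cause of these differences was not tested.

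Of 2532 alternative values of the 143 named genes 2514 stayed on their side of the threshold, 15 moved past it (7 of sex-linked genes, 4 of Adamdec1, 3 of Nrn1 and 1 of Lrmda), 3 lost it, all Eif2s3y, and 0 turned direction while called. The 3 lost calls were the replicate block (adjusted p = 0.067), the fit without WT replicate 3 (0.0501) and a dim probe set by itself (0.644). Only Eif2s3y passed in the main fit, so most values that stayed on their side did so by not passing. In at least 1 setting 19 of the 143 named genes changed sign. Of 299 alternative values of the 20 other lists 291 stayed on their side and 7 were newly called. These calls, at the preset correlation, were erythroid (0.0137) and DNA replication genes (0.0347) lower without WT replicate 1, mast cell genes higher without WT replicate 2 (0.0496), and, with both left out, mast cell (0.0238) and NF-kappaB genes (0.000437) higher and DNA replication (0.0383) and mitosis genes (0.00941) lower. With an estimated correlation, a setting chosen after seeing the data, the calls without 1 array ended (0.782, 0.711 and 0.808). This setting was not run with both arrays left out, so those calls were not checked in that way.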

Other observations

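The tests of WT replicate 2 and of a genotype effect on late granulocyte genes were chosen after those values were seen, and the tests of RNA ends, of X-linked genes, of the Eef1a1 neighbourhood and of regrouped arrays before.

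Lists not described in the results above gave no call in the camera test over all arrays. Apoptosis regulators had 14 of 19 members higher (camera adjusted p = 0.571), with the initiator caspase gene Casp9 at a log2 fold change of 0.31 ± 0.11 and the pro-apoptotic gene Bcl2l11 at -0.28 ± 0.09, a direction that 2 of its 5 probe sets had. The p53 targets had 10 of 19 higher (adjusted p = 0.571), with Btg2, an antiproliferative gene, at -0.60 ± 0.14 by its brightest probe set, the other overlapping between the groups. Inflammatory NF-kappaB targets had 12 of 20 higher (adjusted p = 0.571), and the receptor antagonist gene Il1rn had 1.58 ± 0.39, with all 3 of its probe sets higher. Immediate early genes had 5 of 14 higher (adjusted p = 0.826). Mean and median log2 fold change differed in sign for the Notch pathway, dendritic, MHC class II, stromal and p53 lists.

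WT replicate 2 showed Xist signal together with reduced Y-linked signal: 6 of 6 probe sets, 3 of Xist and the brightest of Eif2s3y, Uty and Kdm5d, lay on the female side of WT replicates 1 and 3, but of the 7 probe sets of these Y-linked genes with an unadjusted p under 0.05 only 5 were lower there, and 1 of Uty was highest there (5.54 against 5.40 and 4.76). Its Xist probe sets held 8.66% to 24.8% of the N1-IC signal, while 48.3% to 71.4% was missing from the brightest Y-linked probe sets and -41.3% to 81.8% from those 7, so the share of female RNA stays open. A wrong label, with WT replicate 2 from a female alone, is argued against. The mean of these 3 Y-linked genes lay 4.83 log2 units above the highest N1-IC array. Other label errors were not tested. Carried-over N1-IC RNA is argued against by 1 gene alone, Adamdec1. Outside the X inactivation list, it alone was over 2 log2 units higher in every N1-IC array than in WT replicates 1 and 3. Its value had been seen when the rule was set, and a first version of the rule had asked for more such genes. In WT replicate 2 Adamdec1 lay 0.307 log2 units above the averaged signal of WT replicates 1 and 3 (3.73 against 3.72 and 3.05), where the lowest Xist share gives 5.39. The low values in these comparisons lay below the lower quartile of their arrays, so the sizes of the differences are uncertain. Of abundant erythroid genes chosen after their values were seen, Car1 was at 12.44 in WT replicate 2, against 4.37 and 8.64 in WT replicates 1 and 3, and Hba-a1 at 4.07, near its 3.61 and 3.84 in WT replicates 1 and 3. Admixed female cells, possibly of the erythroid lineage given Klf1 and Ermap, remain a hypothesis. The sort for YFP and against lineage markers would select against recipient or support cells, but its purity was not checked here. The sex of recipient and support cells is not given in the sources used here. Cell type and origin of any admixed cells were not tested.

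Late granulocyte genes were lower in WT replicate 1 than on the other arrays. Degraded RNA is argued against by the control probe sets, since 0 of 2 control genes (beta-actin and Gapdh) had a difference between 3' and 5' probe sets outside the range of the other arrays (0.417 to 0.493 and 0.513 to 0.547 over all 6), although these controls are among the brightest signals. Without that array the mean log2 fold change was 0.089 with a 95% interval over arrays of -0.532 to 0.71, against 0.813 over all arrays. The array was left out because it was seen to be low, so the fall was built in. This comparison therefore cannot decide on a genotype effect, which stays open, as does 0. A difference in the maturity of the sorted cells of that sample may be involved and was not tested.

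Sex and genotype cannot be told apart for the 1386 autosomal genes with an unadjusted p under 0.05, because all WT samples were male and all N1-IC samples female. Among X-linked genes 8.27% (51 of 617) had such a p, against 7.96% of autosomal genes (Fisher's exact test, two-sided, p = 0.762), which leaves the part of sex open. Genes carried along with the engineered allele were tested as a hypothesis on the 200 measured genes nearest to Eef1a1, of which 7% (14) had such a p, against 7.97% of other autosomal genes (Fisher's exact test, two-sided, p = 0.695), so no excess was found and a short segment stays open.

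The 6 arrays allow 10 splits of 3 against 3, too few for a share under 0.05. For genes past the adjusted threshold the real split gave 1 and the highest other split 0, so 1 split of 10 reached the real value. For an unadjusted p under 0.05 the real split gave 1452 genes and the highest other 1516, which 2 of 10 splits reached or passed. For called lists the real split gave 4 and the highest other 7, and 6 of 10 splits called as many.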
